A study of Mus musculus with 30 samples.

How the data were processed

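Total RNA from mouse brain tumors and normal brain, extracted with Trizol per the labels and labelled with the Ambion WT expression kit, was measured on 30 Affymetrix Mouse Gene 1.0 ST arrays. The submitters' processing notes name Affymetrix Power Tools with MAS5 and RMA, without versions, and do not state how arrays were normalized to each other. The deposited values are log2 signal, 1 per probe set and array, from 0.133 to 16.1, with array medians from 7.03 to 7.30. The arrays do not share 1 distribution, so the deposited values were not themselves quantile normalized as a set. Whether the arrays were normalized to each other before the summary to probe sets is not known. GFAP hippocampus tumors 5 to 7 had medians of 7.03 to 7.07. No 2 columns were identical; the highest correlation between arrays was 0.996 and the lowest among the 8 normal arrays 0.982. Log2 signal includes background, so low values do not measure absence and differences between dim genes are compressed.

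The table held 35556 probe sets, of which 21789 named 1 gene symbol, 1621 several and 12146 none; 21698 of those with 1 symbol matched a gene in the RefSeq table of GRCm38.p6, whose symbols and gene types were used. One probe set was kept for each gene, the one with the highest mean over the 30 arrays, which left 19938 genes (999 had more than 1 probe set). No gene was removed for low signal. Probe sets with several symbols or none, 13767 in number, were tested apart and counted without names. The values were used as deposited, without further scaling.

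Groups came from the labels, by promoter of the injected construct and brain region. limma 3.58.1 in R 4.3.3 fitted 7 group means to all 30 arrays with the spread between arrays pooled over groups, and 11 contrasts were tested: 4 tumor groups against the normal tissue of their region, SYN1 against GFAP in cortex, NES against GFAP in hippocampus, the 3 pairs of regions among GFAP tumors, normal hippocampus against normal cortex, and the interaction of tumor and region for GFAP tumors. Genes were called at Benjamini-Hochberg adjusted p under 0.05 within each contrast. Nothing in the labels says that the arrays came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The number of arrays, 3 to 7 in a group, limits the precision. Errors are standard errors of the limma fit.

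A gene was named where it was among the 10 largest positive or 10 largest negative log2 differences of a contrast with adjusted p under 0.05 and groups that did not overlap (no such demand for the interaction), where it belonged to a list, or where it was a promoter or candidate vector gene. Predicted genes and probe sets with several genes were counted and not named. Genes picked from within a list as examples were picked after their values were seen. Gene functions are general background.

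There were 27 lists, with 386 genes of which 350 were measured: neuron, synapse, astrocyte, oligodendrocyte, oligodendrocyte precursor, neural stem and progenitor, microglia and macrophage, T and NK cell, B cell and neutrophil, red blood cell, endothelial, mural cell and fibroblast, ependymal and choroid plexus, cell cycle, p53 targets, RAS and MAPK response, hypoxia and glycolysis, extracellular matrix, interferon and antigen presentation, the proneural, classical, mesenchymal and neural glioblastoma subtypes, cortex region, hippocampus region, striatum and SVZ region, and promoter and candidate vector genes. They were put together from general knowledge and 12 of them were read as cell type markers. Each list was tested with camera of limma at its preset correlation of 0.01 between genes and with an estimated correlation, adjusted over the 27 lists of each contrast. Counts over all genes used the adjustment over 19938 genes, and counts over the list alone adjusted within the list.

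The contrasts, the lists, the choice of probe set, the thresholds, the naming of genes and these alternatives were set before the data were examined: centring each array on its median, quantile normalization, leaving out the 30% of genes with the lowest mean, the mean of a gene's probe sets, trend and robust settings of eBayes, only the arrays of the groups compared, array weights, adjusted p under 0.01, a change of at least 2-fold, the replicate number as a block, each array left out in turn, GFAP hippocampus tumors 1 to 4 only, and fry in place of camera. Leaving out the 4 arrays that stand apart, using GFAP hippocampus tumors 5 to 7 only, and testing the promoter genes without GFAP cortex tumor 1, were chosen after the data were seen. Calls were also counted for up to 100 regroupings of the arrays of each contrast, with the spread pooled over all 30 arrays each time.

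Whether replicate numbers pair samples across groups was checked from correlations of residuals in 10 contrasts. Pair correlations ran from -0.394 to 0.565. Only GFAP hippocampus and GFAP cortex tumors 1 to 4 had every equal-numbered pair above 0.1 (0.277 to 0.306, mean 0.29, against a mean of -0.044 for unequal numbers). No equal-numbered pair of these was the best match in both directions, so the pairing is a hint. The count with the number as a block is given beside the unblocked one for that contrast.

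The procedure was tested on simulated data with planted differences in the same design. The noise was independent between arrays and genes, with the same SD for a gene in all arrays. For GFAP cortex tumors against normal cortex it called 16.4%, 70.1% and 95.5% of the genes planted at 0.5, 1 and 2 log2, for GFAP hippocampus tumors 25.4%, 77.6% and 97.0%, for SVZ against cortex tumors 11.9%, 67.2% and 89.4%, and for the interaction 5.97%, 56.7% and 86.4%. The false share of calls was 6.43%, 2.67%, 4.58% and 3.60%. In the real arrays the spread was unequal, with array weights from 0.105 in GFAP cortex tumor 1 to 4.365 in NES hippocampus tumor 2. The simulated shares therefore do not give the error of the real contrasts. Raw array files were not used here.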

Results

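The arrays profiled mouse brain tumors that followed injection of Cre constructs driven by the GFAP, SYN1 or NES promoter, beside normal cortex and normal hippocampus. GFAP is an astrocyte gene, SYN1 a neuron gene and NES a gene of neural progenitors, so the question was how much tumors begun with each promoter differed from normal brain and from each other. There were 30 arrays: 4 of normal cortex, 4 of normal hippocampus, 4 of GFAP cortex tumors, 4 of SYN1 cortex tumors, 7 of GFAP hippocampus tumors, 4 of NES hippocampus tumors and 3 of GFAP tumors of the subventricular zone (SVZ), and 19938 genes were tested. The labels name no normal SVZ sample, so SVZ tumors were compared with the other GFAP tumors only.

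Normal brain and tumor arrays separated on the first principal component, which held 56.6% of the variance over all genes. The 8 normal arrays lay between 69.8 and 85.1 on it. The second component (14.2%) set 4 tumor arrays apart from the rest of their groups: GFAP cortex tumor 1 at -67.1, and GFAP hippocampus tumors 5, 6 and 7 at -74.7, -55.9 and -61.8. Tumors 5 to 7 are listed apart from the other 27 samples. GFAP cortex tumor 1 also had a narrow spread of values (interquartile range 1.88 against 2.74 to 2.81 in tumors 2 to 4) and a mean correlation of 0.868 with its group. Counts that rest on these groups are therefore also given without these 4 arrays, a choice made after seeing the data.

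**Figure D1:**
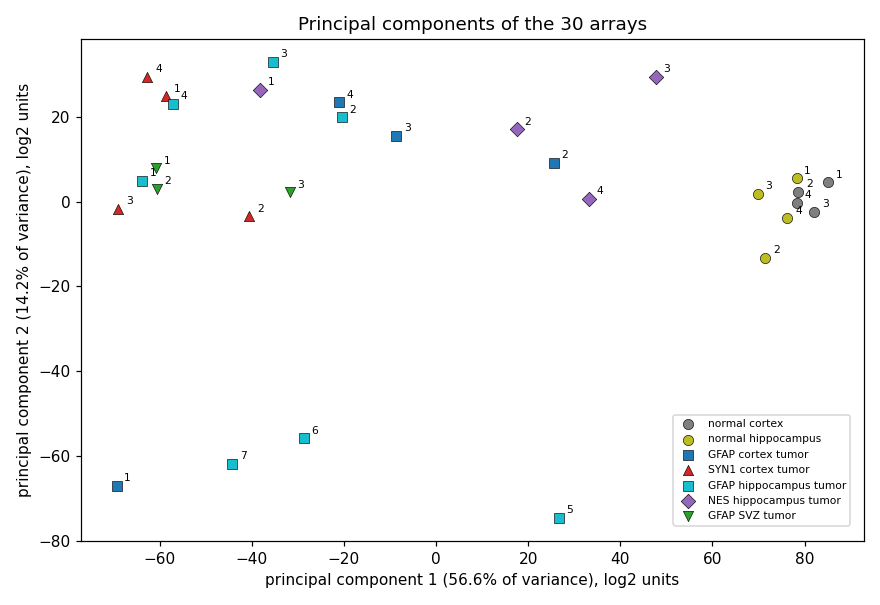
Principal components of the 30 arrays over 19938 genes. The first component holds 56.6% of the variance and the second 14.2%; numbers mark the replicates.

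Of the promoter genes, the one for the progenitor filament nestin, Nes, rose in all 4 tumor groups that had a normal control. Its log2 difference was 3.53 ± 0.49 (SE, 4 arrays against 4, limma adjusted p = 2.45e-05) in GFAP cortex tumors and 3.63 ± 0.43 (7 against 4, adjusted p = 6.69e-07) in GFAP hippocampus tumors. It was 3.73 in SYN1 cortex tumors and 2.65 in NES hippocampus tumors (limma adjusted p = 2.21e-06 and 0.00094). The synaptic vesicle gene Syn1 fell in GFAP cortex tumors (log2 difference -2.56 ± 0.60, adjusted p = 0.00239; -1.67, limma adjusted p = 0.0114 without GFAP cortex tumor 1), GFAP hippocampus tumors (-2.58 ± 0.53, adjusted p = 0.000373) and SYN1 cortex tumors (-3.20, adjusted p = 0.000107). It did not pass in NES tumors (-0.91, limma adjusted p = 0.394). The astrocyte filament gene Gfap lay 1.04 to 1.59 log2 above normal tissue and passed in no group (limma adjusted p = 0.257, 0.0891, 0.25 and 0.158 in the same order). The missing calls for Gfap in the GFAP groups hung on GFAP cortex tumor 1, which had a Gfap level of 6.89 against 10.7 to 11.9 in GFAP cortex tumors 2 to 4. Without that array the difference was 2.19 in GFAP cortex tumors (limma adjusted p = 0.00201) and passed in GFAP hippocampus tumors as well (adjusted p = 0.00828). In the latter it did not pass without all 4 arrays that stand apart (0.84, limma adjusted p = 0.0668). Cdkn2a, a cell cycle inhibitor gene, rose in all 4 (1.64, 2.38, 2.46 and 1.37; limma adjusted p = 0.00103, 1.56e-06, 3.99e-06 and 0.0113). Nf1, a negative regulator of RAS, passed in none (-0.58, -0.51, -0.36 and -0.04). In GFAP hippocampus tumors Nf1 passed without GFAP cortex tumor 1 (limma adjusted p = 0.0389) and not without the 4 arrays (-0.10, adjusted p = 0.569). Rb1 was lower in GFAP hippocampus tumors only (-0.81, limma adjusted p = 0.0363), and did not pass without the 4 arrays (-0.45, adjusted p = 0.0626). Trp53 and Hras have no probe set that names that gene alone and were not analysed here. The labels do not give the cassettes of the constructs. Of the 6 measured genes in this list, 2 were higher and 1 lower in GFAP cortex tumors, against 2 and 2 adjusted over the list alone and 3 and 1 without the 4 arrays; camera gave adjusted p = 0.188.

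**Figure D2:**
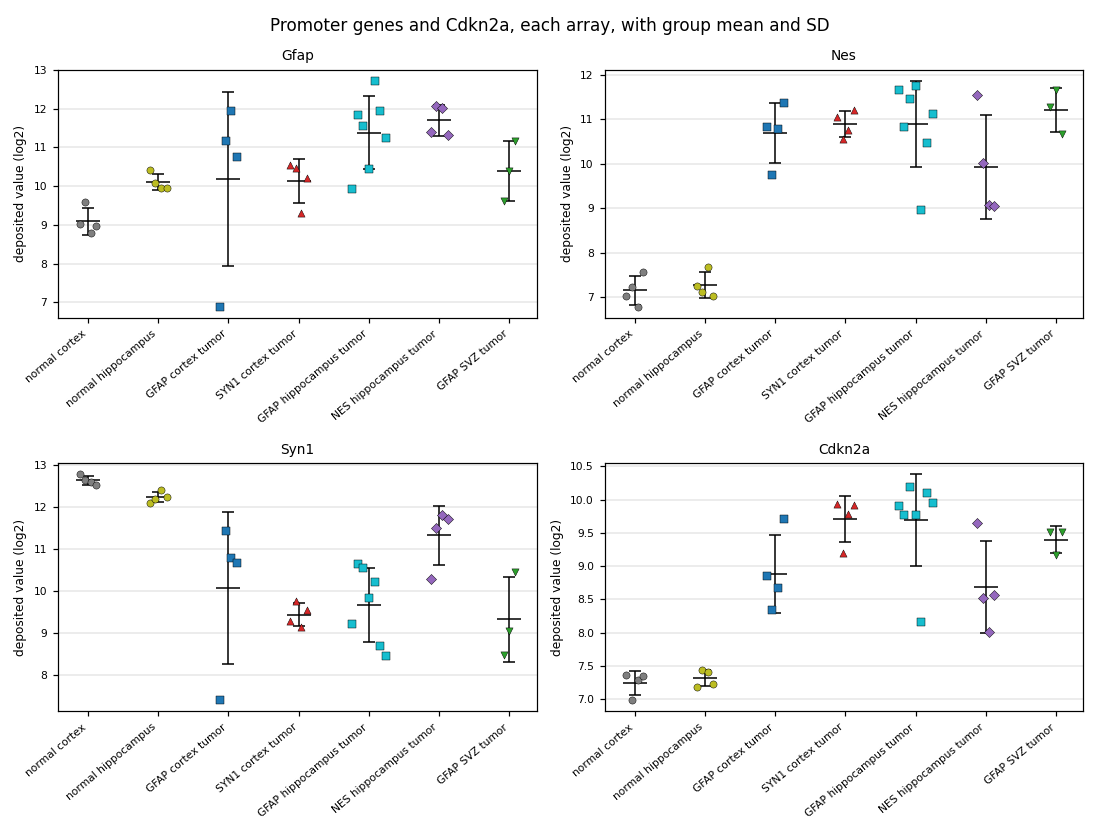
Levels of the promoter genes and of candidate vector genes in each array. Nes lay 2.65 to 3.73 log2 above normal tissue in the 4 tumor groups with a normal control, and Syn1 lay at -2.56 to -3.20 in 3 of them.

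GFAP cortex tumors carried more transcript of extracellular matrix genes than normal cortex and less of neuron genes. Timp1, which encodes an inhibitor of matrix metalloproteinases, rose most (log2 difference 4.32 ± 0.62, 4 arrays against 4, limma adjusted p = 3.77e-05). The matrix glycoprotein gene Tnc was 19.5-fold higher (4.28 ± 0.66, adjusted p = 6.77e-05). Anxa1, a regulator of inflammation, was 16-fold higher. The calcium-binding S100a6 rose by 3.87, Thbs1 by 3.84, the urokinase gene Plau by 3.81, the membrane protein gene Emp1 by 3.89 and the fibronectin receptor subunit Itga5 by 3.69. Lamp5 (-3.67) and Sst (-3.30), which mark cortical interneurons, and the projection neuron transcription factor Neurod6 (-3.27) fell. The activity-regulated genes Arc and Nr4a1 were 9.74-fold and 7.54-fold lower (limma adjusted p = 2.26e-06 for both). Rgs4 (-3.05), Kcnv1 (-3.03), Cacng3 (-2.96) and Vxn (-2.93) fell as well. Each of these genes had every tumor array on one side of every normal array. Of 19938 genes 5536 (27.8%) changed by limma, 1794 higher and 3742 lower. Without GFAP cortex tumor 1 the count was 4269 (1634 and 2635), and without all 4 arrays that stand apart 6644 (2563 and 4081). Quantile normalization gave 2831 higher and 3255 lower. The groups lay fully apart in 7405 genes (37.1%), where chance gives 2.86%.

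Neuron and synapse genes were lower in GFAP cortex tumors and proliferation, matrix, microglia and macrophage, and interferon genes higher. Of 22 neuron genes 18 were lower, 0 higher and 4 did not pass (20 lower adjusted over the list alone; camera adjusted p = 6.75e-07, adjusted p = 0.297 with an estimated correlation). Without the 4 arrays 14 were lower. GFAP cortex tumor 1 had a neuron score, the mean over the list of differences from the 8 normal arrays, of -3.84 against -1.54 to -0.73 in tumors 2 to 4. Of 14 synapse genes 11 were lower (13 over the list alone; adjusted p = 3.31e-06, adjusted p = 0.297 with an estimated correlation; 10 without the 4 arrays). Oligodendrocyte genes were lower in 10 of 11 (11 over the list alone; adjusted p = 0.000586, adjusted p = 0.364 with an estimated correlation), but in 4 without the 4 arrays. Mbp, a myelin gene, was lower at -1.70. Cortex region genes were lower in 10 of 11 (10 over the list alone and 10 without the 4 arrays; camera adjusted p = 4.98e-06, adjusted p = 0.133 with an estimated correlation). Among them were Tbr1 (-2.65) and Dkkl1 (-2.57).

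Cell cycle genes were higher in 21 of 25 in GFAP cortex tumors (21 over the list alone and 21 without the 4 arrays; camera adjusted p = 9.88e-17, adjusted p = 0.182 with an estimated correlation). Cdk1 rose by 3.06 and Top2a by 2.52. All 19 extracellular matrix genes rose (19 over the list alone, 17 without the 4 arrays), among them Mmp2 (3.28) and Fn1 (2.53). camera gave adjusted p = 1.58e-18, adjusted p = 0.128 with an estimated correlation. Tumor 1 had the highest matrix score, 3.14 against 1.47 to 2.44. Microglia and macrophage genes were higher in 15 of 20 (15 over the list alone, 16 without the 4 arrays; adjusted p = 3.67e-13, adjusted p = 0.128 with an estimated correlation). The lysozyme gene Lyz2 rose by 3.64 and the integrin gene Itgam by 1.96. Tumor 1 scored 0.82 and the others from 1.29 up. Interferon and antigen presentation genes were higher in 14 of 16 (15 over the list alone, 13 without the 4 arrays; adjusted p = 4.49e-12, adjusted p = 0.128 with an estimated correlation). T and NK cell genes were higher in 0 of 12 (0 over the list alone, 1 without the 4 arrays; adjusted p = 0.188, adjusted p = 0.521 with an estimated correlation). Mesenchymal subtype genes were higher in 14 of 20, Cd44 by 2.99 (16 over the list alone, 14 without the 4 arrays; adjusted p = 1.08e-14, adjusted p = 0.128 with an estimated correlation). Mural cell and fibroblast genes were higher in 8 of 14 (9 over the list alone; adjusted p = 3.31e-06, adjusted p = 0.182 with an estimated correlation), and in 8 with 1 lower without the 4 arrays.

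GFAP hippocampus tumors shared most of these changes and added a loss of hippocampal neuron genes. Lcn2, an acute-phase lipocalin, was 28.5-fold higher than in normal hippocampus (log2 difference 4.83 ± 0.63, 7 arrays against 4, limma adjusted p = 1.9e-06) and Lyz2 17.4-fold higher (4.12 ± 0.37, adjusted p = 1.13e-08). Anxa1 rose by 4.19, Plau by 4.13, Tnc by 3.89 and the protease inhibitor A2m by 3.68. So did the focal adhesion gene Tes by 3.65, the endothelial proteoglycan gene Esm1 by 3.75 and the heme oxygenase gene Hmox1 by 3.93. Neurod6 was 30.1-fold lower (-4.91 ± 0.45, adjusted p = 1.39e-08) and the GABA receptor subunit Gabra5 25.4-fold lower (-4.67 ± 0.60, adjusted p = 1.84e-06). The dendritic gene Ddn (-4.21), the protocadherin Pcdh20 (-4.14), St6galnac5 (-3.91), Epha6 (-3.61), Sst (-3.61), Sowaha (-3.58) and Mal2 (11.3-fold) were lower. The immediate early gene Nr4a3 fell by 3.46 (limma adjusted p = 5.06e-10). By limma 8245 genes (41.4%) changed, 3213 higher and 5032 lower, and 10443 (5187 and 5256) without tumors 5 to 7 and GFAP cortex tumor 1. With the replicate number as a block 4685 were higher and 4340 lower, with tumors 1 to 4 only 4676 and 4387, and with tumors 5 to 7 only 2313 and 6422, so the balance of directions is not settled. The groups lay fully apart in 5229 genes (26.2%; chance 0.606%).

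All 11 hippocampus region genes were lower in GFAP hippocampus tumors (11 over the list alone, 10 without the 4 arrays), with the dentate granule cell factor Prox1 at -2.61, Lct at -2.70 and Fibcd1 at -2.43. This was the only list whose camera result passed in this comparison with both correlations (adjusted p = 2.18e-09, adjusted p = 0.0182 with an estimated correlation). Without the 4 arrays it passed by camera at the preset correlation only (adjusted p = 2.27e-07, adjusted p = 0.0933 with an estimated correlation). Neuron genes were lower in 16 of 22 (19 over the list alone and 19 without the 4 arrays; adjusted p = 7.18e-05, adjusted p = 0.484 with an estimated correlation). Synapse genes were lower in 14 of 14 (14 and 14; adjusted p = 5.75e-06, adjusted p = 0.351 with an estimated correlation). Cell cycle genes were higher in 24 of 25 (24 over the list alone, 25 without the 4 arrays; adjusted p = 5.91e-16, adjusted p = 0.185 with an estimated correlation). Top2a rose by 3.42. Extracellular matrix genes were higher in 16 of 19 (19 and 19; adjusted p = 3.66e-11, adjusted p = 0.163 with an estimated correlation). Microglia and macrophage genes were higher in 16 of 20 (16 and 16; adjusted p = 2.35e-10, adjusted p = 0.163 with an estimated correlation). The resting microglia gene P2ry12 did not pass (-0.79). Hypoxia and glycolysis genes were higher in 11 of 16 (11 over the list alone, 12 without the 4 arrays; adjusted p = 6.55e-06, adjusted p = 0.255 with an estimated correlation). Adm rose by 2.73, Hk2 by 2.19 and Vegfa by 0.94. Endothelial genes were higher in 8 of 12 (8 and 10; adjusted p = 4.86e-05, adjusted p = 0.163 with an estimated correlation), Vwf by 1.31. RAS and MAPK response genes were higher in 10 of 18 and lower in 2 (11 and 2 over the list alone, 13 and 1 without the 4 arrays; adjusted p = 0.00182, adjusted p = 0.484 with an estimated correlation). Ccnd1 rose by 2.33 and Myc by 1.93, and Egr1 fell by 0.94. Tumors 5, 6 and 7 had neuron scores of -0.85, -2.11 and -2.47 and tumors 1 to 4 -2.66 to -1.28.

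SYN1 cortex tumors, begun with a neuronal promoter, had less neuronal transcript than normal cortex and more of the matrix genes seen in GFAP tumors. Thbs1, a matrix glycoprotein gene, was 31.1-fold higher (log2 difference 4.96 ± 0.65, 4 arrays against 4, limma adjusted p = 2.35e-06), Anxa1 29.4-fold (4.88, adjusted p = 1.18e-06) and Timp1 29.3-fold (4.87, adjusted p = 1.64e-06). Dynap rose by 5.04 with a wide error (SE 1.36, adjusted p = 0.00391), the acetylcholine receptor subunit Chrna1 by 4.86, the BMP antagonist Grem1 by 4.73, the NKG2D ligand Raet1d by 4.70, Gpr149 by 4.65 and Fndc3c1 by 4.73. Lamp5 was 26.6-fold lower (-4.74 ± 0.66, adjusted p = 4.46e-06), Neurod6 21.5-fold and Sst 18.9-fold. The channel and pump genes Kcnh7 (-4.18), Kcnv1 (-4.03) and Atp2b2 (-4.06) fell. So did Mal2 (-4.15), Hpcal4 (-4.11), Rgs4 (-4.07) and Ddn (-4.03). By limma 7723 genes (38.7%) changed, 3627 higher and 4096 lower, and 9760 genes (49.0%; chance 2.86%) kept the groups fully apart.

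Neuron genes were lower in 20 of 22 in SYN1 cortex tumors (22 over the list alone; camera adjusted p = 5.99e-09, adjusted p = 0.281 with an estimated correlation). Among them were Slc17a7, the vesicular glutamate transporter of excitatory neurons (-3.87), and Snap25 (-3.17). All 7 genes of the neural subtype moved down or did not pass: 5 were lower (6 over the list alone; adjusted p = 0.00238, adjusted p = 0.302 with an estimated correlation). The score was -3.06 in tumor 3 and -1.99 to -1.93 in the others. Astrocyte genes were lower in 8 of 14 and higher in 1 (9 and 1 over the list alone; adjusted p = 0.04, adjusted p = 0.539 with an estimated correlation). Oligodendrocyte genes were lower in all 11 (11; adjusted p = 8.13e-05, adjusted p = 0.336 with an estimated correlation) and striatum and SVZ region genes in 8 of 13 (10; adjusted p = 0.0128, adjusted p = 0.519 with an estimated correlation). Cell cycle genes were higher in 24 of 25 (25 over the list alone; adjusted p = 2.73e-14, adjusted p = 0.27 with an estimated correlation), Cdk1 by 3.73. All 19 matrix genes were higher (19; adjusted p = 8.03e-13, adjusted p = 0.185 with an estimated correlation). Interferon and antigen presentation genes were higher in 15 of 16 (15; adjusted p = 1.16e-09, adjusted p = 0.198 with an estimated correlation), Cxcl10 by 3.47. Mesenchymal subtype genes were higher in 17 of 20 (18; adjusted p = 4.17e-12, adjusted p = 0.185 with an estimated correlation), Cd44 by 3.71. The Notch ligand Jag1 rose by 4.27 and the receptor gene Egfr by 1.67.

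In NES hippocampus tumors interferon and antigen presentation genes were among those raised most. Cxcl10, an interferon-induced chemokine, was 15.5-fold higher (log2 difference 3.95 ± 0.68, 4 arrays against 4, limma adjusted p = 0.000499), the MHC class II gene H2-Aa 13.5-fold (3.75 ± 0.47, adjusted p = 1.21e-05) and Ifit3 13.3-fold (3.74 ± 0.58, adjusted p = 0.00017). Cd74, Ifit1, the monocyte gene Ms4a6c and Lyz2 rose by 3.69, 3.56, 3.54 and 3.46, Lcn2 by 4.02, A2m by 3.45 and the protease gene Klk6 by 3.42. The genes that fell included regional genes of the normal hippocampus. Neurod6 (-3.34), Pcdh20 (7.98-fold), Cabp7 (-2.47), Slc9a4 (-2.46), Epha6 (-2.40), Spink8 (-2.40) and Tdo2 (-2.38) were lower. Syna lay at -3.001 and Lct was 5.37-fold lower, with limma adjusted p of 5.48e-10 and 9.98e-11. By limma 1706 genes (8.56%) changed, 1135 higher and 571 lower, but centring the arrays on their medians gave 955 higher and 1461 lower and quantile normalization 1260 and 1003. Centring moved the median log2 difference of all genes from -0.05 to -0.20. The count was 702 without NES tumor 1, 1131 without normal hippocampus 1 and 1081 without normal hippocampus 4. The groups lay fully apart in 4905 genes (24.6%; chance 2.86%).

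Interferon and antigen presentation genes were higher in 15 of 16 in NES tumors (16 over the list alone; camera adjusted p = 1.34e-23, adjusted p = 0.0136 with an estimated correlation), with array scores of 3.14, 2.60, 2.14 and 2.03. Microglia and macrophage genes were higher in 15 of 20 (17; adjusted p = 2.89e-19, adjusted p = 0.0463 with an estimated correlation). Hippocampus region genes were lower in 7 of 11 (9; adjusted p = 6.31e-15, adjusted p = 0.00106 with an estimated correlation), Prox1 at -1.81 and Fibcd1 at -2.17. Cell cycle genes were higher in 19 of 25 (22; adjusted p = 1.86e-22, adjusted p = 0.111 with an estimated correlation), Mki67 by 2.63. Matrix genes were higher in 11 of 19 (13; adjusted p = 1.67e-11, adjusted p = 0.111 with an estimated correlation). Of 22 neuron genes none passed, alone or over the list (camera down, adjusted p = 0.0355, adjusted p = 0.609 with an estimated correlation). Array scores were -1.57, -0.48, -0.17 and -0.64. Synapse genes were lower in 1 of 14 (3 over the list alone; adjusted p = 0.000412, adjusted p = 0.434 with an estimated correlation), with array scores from -1.95 to -0.43. Neural stem and progenitor genes were higher in 4 of 15 and lower in 1 (5 and 1 over the list alone; adjusted p = 0.00241, adjusted p = 0.387 with an estimated correlation). Cd24a, Sox4 and Vim were higher and Hes5 lower, as in the other 3 tumor groups. Oligodendrocyte precursor genes were higher in 1 of 10 (1; adjusted p = 0.00633, adjusted p = 0.434 with an estimated correlation).

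**Figure D3:**
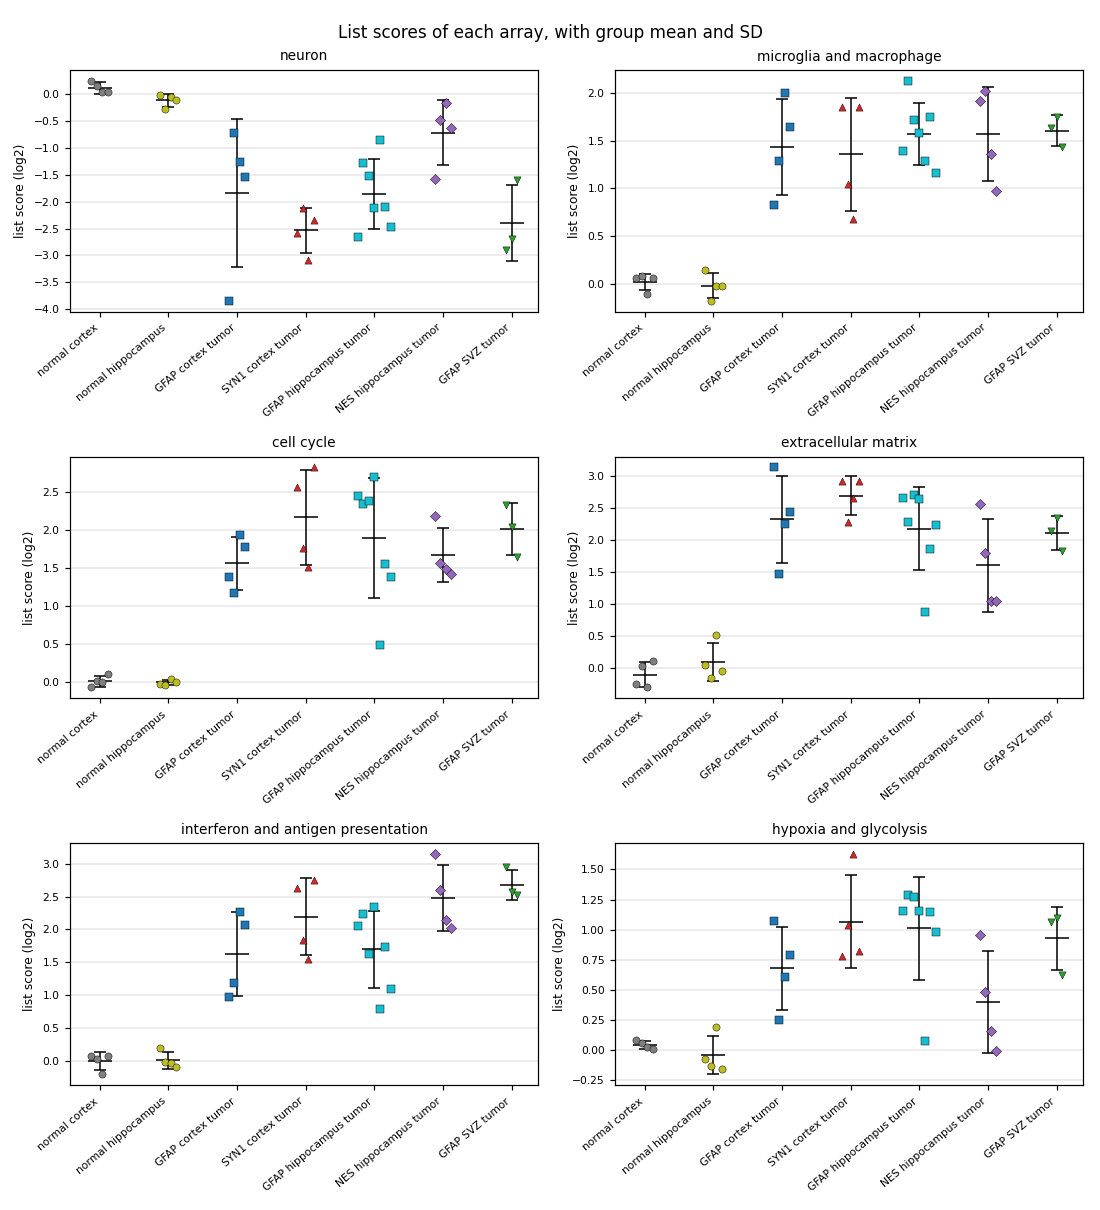
Gene list scores of each array, as the mean difference from the 8 normal arrays. Neuron scores were -3.84 in GFAP cortex tumor 1 and -0.17 in NES tumor 3.

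More changes against normal tissue were shared between tumor groups than independent changes would give. GFAP cortex and GFAP hippocampus tumors, which have no control array in common, had 1543 genes higher in both and 2866 lower in both, where independent changes would give 289 and 944; 16 genes changed in opposite directions (1056 if independent). The log2 differences correlated over all genes at 0.864 (Spearman 0.777). SYN1 cortex and NES hippocampus tumors differed in promoter and region at once. Of their 7723 and 1706 changes 1427 were shared in direction, most of the NES changes and a small part of the SYN1 changes. They had 990 genes higher in both and 437 lower in both (206 and 117 if independent) and 20 in opposite directions (337), with a correlation of 0.763 (Spearman 0.722). Without the 4 arrays that stand apart, the GFAP pair shared 5168 genes in the same direction against 4409 with them.

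**Figure D4:**
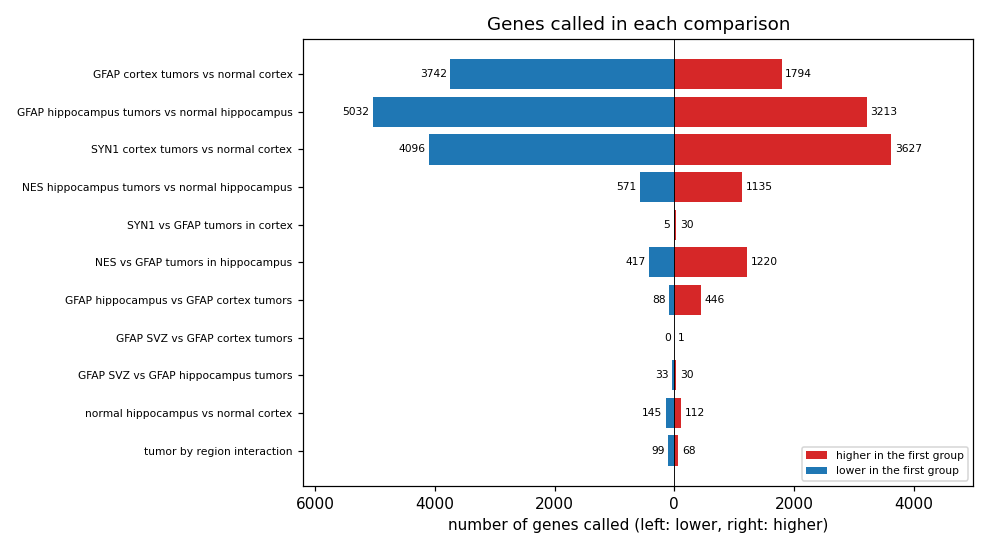
Genes higher and lower at adjusted p under 0.05 in each comparison. The counts run from 1 in SVZ against cortex tumors to 8245 in GFAP hippocampus tumors against normal hippocampus.

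In the cortex, SYN1 and GFAP tumors differed in few genes. Efnb1, an ephrin ligand of neural progenitors, was 2.35-fold higher in SYN1 tumors (log2 difference 1.24 ± 0.17, 4 arrays against 4, limma adjusted p = 0.0026). The prolactin family gene Prl8a9 was 4.53-fold higher (2.18 ± 0.37, adjusted p = 0.0163), and the potassium channel Kcnn4 3.61-fold (1.85, adjusted p = 0.0293). Also higher were Slc25a21 3.29-fold, Lncenc1 3.22-fold, the interferon-induced Oasl1 3.07-fold, Stac 2.97-fold, Adcy7 2.88-fold, the cytokine gene Tslp 2.61-fold and Spin4 2.29-fold. The growth factor receptor Fgfr2 (-1.26), Lbp (-1.30) and Cmya5 (-0.62) were lower. By limma 35 genes changed, 30 higher and 5 lower, and 4 with only the groups compared in the fit. There were 2933 at unadjusted p under 0.05, and 1511 (7.58%; chance 2.86%) kept the groups apart. The count turned on single arrays. It was 1132 (232 higher and 900 lower) without GFAP cortex tumor 1, 1 without GFAP cortex tumor 2 and 7 without tumor 3. It was 66 without SYN1 tumor 1, 6 without SYN1 tumor 2 and 1 without SYN1 tumor 3. Efnb1 kept its call in each of these, and every other named gene lost its own in at least 1. Without all 4 arrays that stand apart it was 2655, 1106 higher and 1549 lower. With the pooled spread, regrouping the 8 arrays called up to 1468 genes, so the contrast of promoters was not separated from chance.

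Neuron and synapse genes lay lower in SYN1 than in GFAP cortex tumors without passing 1 by 1. Of 22 neuron genes 0 changed, also over the list alone (camera adjusted p = 6.75e-06, adjusted p = 0.562 with an estimated correlation), and of 14 synapse genes 0 (adjusted p = 1.27e-05, adjusted p = 0.562 with an estimated correlation). Without the 4 arrays that stand apart 13 neuron and 10 synapse genes were lower; GFAP cortex tumor 1 had the lowest neuron score of the 8. Mesenchymal subtype genes were higher in 1 of 20, Traf1 by 1.06 (3 over the list alone and 3 without the 4 arrays; adjusted p = 0.00378, adjusted p = 0.562 with an estimated correlation). Astrocyte genes had 0 of 14 lower and 8 lower without the 4 arrays (camera adjusted p = 0.0136, adjusted p = 0.562 with an estimated correlation).

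In the hippocampus, NES tumors were compared with GFAP tumors. Fgf1, a growth factor gene of neurons, was 3.07-fold higher (log2 difference 1.62 ± 0.22, 4 arrays against 7, limma adjusted p = 0.00127), and Sst 5.65-fold (2.50 ± 0.49, adjusted p = 0.0129). So were Dbpht2 4.61-fold, Gabra5 3.86-fold, Rab33a 3.56-fold, Efhd1 3.42-fold, Clvs1 3.36-fold, Rgs7 3.33-fold, Ak5 3.17-fold and the ephrin gene Efna3 3.02-fold. Syn1 was higher by 1.67 (adjusted p = 0.0492). The platelet factor gene Pf4 (-2.32, adjusted p = 0.0129), the macrophage gene F13a1 (-1.23), Tmsb10 (-1.56), Hnrnpf (-1.21), Rabggtb (-1.16), Cnbp (-1.03) and Zfp345 (-1.04) were lower. The ribosomal protein genes Rpl8 (-1.25), Rpsa (-1.12 ± 0.16, adjusted p = 0.00143) and Rps18 (-1.05) were lower too, as was Cdkn2a (-1.01, adjusted p = 0.0413). By limma 1637 genes changed, 1220 higher and 417 lower, and 0 with only the groups compared in the fit. Centring the arrays gave 731 higher and 1515 lower and quantile normalization 883 and 1267, so the balance of directions is not settled. Centring moved the median of all genes from 0.06 to -0.16.

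The NES against GFAP count fell to 6 without NES tumor 4, 15 without NES tumor 3, and 154 without NES tumor 2. It was 282 without GFAP hippocampus tumor 7, 443 without tumor 6 and 793 without tumor 1. It rose to 3398 without NES tumor 1, 2717 without GFAP hippocampus tumor 2 and 2742 without tumor 5. Fgf1 and Rpsa kept their calls each time, and every other named gene lost its own without NES tumor 3 or 4. Without GFAP hippocampus tumors 5 to 7 and GFAP cortex tumor 1 it was 4218, 2073 higher and 2145 lower. Only 339 genes (1.70%; chance 0.606%) kept the groups fully apart, and regrouping the arrays called up to 5886, so chance was not excluded. Neuron genes were higher in 4 of 22 (4 over the list alone, 15 without the 4 arrays; camera adjusted p = 0.000112, adjusted p = 0.513 with an estimated correlation), Rbfox3 by 1.79. Hypoxia and glycolysis genes were lower in 5 of 16 (7 and 10; adjusted p = 1.02e-06, adjusted p = 0.513 with an estimated correlation), Adm by 1.62 and Hk2 by 1.29. Extracellular matrix genes were lower in 2 of 19 (4 and 7; adjusted p = 0.000148, adjusted p = 0.513 with an estimated correlation). Cortex region genes were higher in 4 of 11 (8 and 7; adjusted p = 0.000927, adjusted p = 0.513 with an estimated correlation). Of 25 cell cycle genes 0 changed, and 17 were lower without the 4 arrays (adjusted p = 0.00327, adjusted p = 0.675 with an estimated correlation).

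GFAP hippocampus tumors were compared with GFAP cortex tumors. Cox7a2, a respiratory chain gene, was 2.31-fold higher in hippocampus tumors (log2 difference 1.21 ± 0.23, 7 arrays against 4, limma adjusted p = 0.00765) and the RNA-binding Cnbp 2.48-fold (1.31 ± 0.25, adjusted p = 0.00765). The ATP synthase gene Atp5mpl (1.49), the elongation factor gene Eef1a1 (1.29), Hnrnpf (1.22) and Gpx4 (1.19) were higher too. The olfactory receptor genes Olfr1116 and Olfr1051 and the microRNA genes Mir463 and Mir450b were called as well, but at group means of 2.78 to 5.45, the level of background, and are not read as expressed. Sfrp1, a WNT antagonist gene, was 2.62-fold lower (-1.39 ± 0.24, adjusted p = 0.00549). Sod3 (-1.26), Podn (-0.81), Btnl5-ps (-0.79), Aloxe3 (-0.72), Mdga1 (-0.70), Il15ra (-0.65), Plb1 (-0.63), Oscar (-0.63) and Msx3 (-0.58) were lower. By limma 534 genes changed, 446 higher and 88 lower, and 0 with only the groups compared in the fit. Centring gave 881 higher and 47 lower, and quantile normalization 85 and 56, under which all 10 named higher genes lost their calls. Centring moved the median of all genes from 0.00 to 0.10. The count was 1421 (889 and 532) without GFAP cortex tumor 1, 252 without cortex tumor 2, and 205 without cortex tumor 3. It was 883, 286 and 220 without hippocampus tumors 5, 6 and 7, and 2090 (1692 and 398) without the 4 arrays that stand apart. With hippocampus tumors 5 to 7 only, 1561 were higher and 3404 lower, so the balance of directions is not settled. Leaving out 1 array took the call from Atp5mpl, both olfactory receptor genes, Mir450b, Podn, Aloxe3, Mdga1, Il15ra or Plb1, and leaving out the 4 took it from Mir463 and Sod3.

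Residuals gave a hint that replicate numbers pair GFAP hippocampus and GFAP cortex tumors 1 to 4, though no pair was the best match in both directions. With the number as a block 1954 genes changed, 1795 higher and 159 lower. That block gives each number an effect shared by all groups. In the other contrasts the mean correlation of equal-numbered pairs was only -0.096 to 0.075. The block also leaves tumors 5 to 7 without partners, and tumors 1 to 4 without a block gave 1924 (1783 and 141), so the changes below are not those of the block alone. Cell cycle genes were higher in 0 of 25 without the block (10 without the 4 arrays; camera adjusted p = 0.0227, adjusted p = 0.966 with an estimated correlation) and in 20 of 25 with it (adjusted p = 5.45e-11, adjusted p = 0.711 with an estimated correlation). Hypoxia and glycolysis genes were higher in 3 of 16 (3 over the list alone; adjusted p = 0.0227, adjusted p = 0.966 with an estimated correlation) and in 4 with the block (adjusted p = 0.00659, adjusted p = 0.785 with an estimated correlation). Hippocampus tumor 5 scored 0.07 and the other 6 0.98 to 1.29. Cortex region genes had 0 of 11 lower (1 over the list alone, 6 without the 4 arrays; adjusted p = 0.0227, adjusted p = 0.966 with an estimated correlation) and 2 with the block (adjusted p = 0.000288, adjusted p = 0.597 with an estimated correlation). Only 326 genes (1.64%; chance 0.606%) kept the groups fully apart.

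SVZ tumors differed from other GFAP tumors in few genes when all arrays were used, and some cytotoxic lymphocyte genes were higher in them than in hippocampus tumors. Against cortex tumors 0 of 22 neuron genes passed (0 over the list alone; camera down, adjusted p = 0.000153, adjusted p = 0.567 with an estimated correlation). In that comparison 10 of 22 neuron, 8 of 14 synapse, 6 of 10 oligodendrocyte precursor and 5 of 14 astrocyte genes were lower without the 4 arrays (adjusted p = 5.85e-09, 2.37e-07, 3.48e-05 and 4.11e-05, and adjusted p = 0.384 for each with an estimated correlation). The endothelial lipase gene Lipg was 2.25-fold higher than in cortex tumors (log2 difference 1.17 ± 0.16, 3 arrays against 4, limma adjusted p = 0.00157) and 2.06-fold higher than in hippocampus tumors (1.04 ± 0.14, 3 against 7, adjusted p = 0.00193). Against hippocampus tumors the chemokine gene Cxcl9 was 6.03-fold higher (2.59 ± 0.49, adjusted p = 0.0206), and the cytotoxic granule gene Nkg7 2.72-fold (1.44 ± 0.25, adjusted p = 0.0206). Also higher were H2-M9 2.97-fold, the ventral forebrain factor Lhx6 2.68-fold, Tnfsf9 2.65-fold, Dmpk 2.44-fold, Bend7 2.37-fold, Plekhf1 2.34-fold and Desi2 2.09-fold. The related factor Lhx8 (-2.37, adjusted p = 0.0384), Pcdhb16 (-1.30), Tmeff1 (-1.07), Gtf2e2 (-1.02) and Nup133 (-1.001) were lower, as were the serine synthesis gene Phgdh (-0.99), Ebna1bp2 (-0.94), Cox4i1 (-0.92), Ro60 (-0.91) and Park7 (-0.88). T and NK cell genes were higher than in hippocampus tumors in 3 of 12, Nkg7 by 1.44, Cd3e by 0.65 and Prf1 by 0.58 (8 over the list alone, 3 without the 4 arrays; camera adjusted p = 3.08e-07, adjusted p = 0.0599 with an estimated correlation). Without the 4 arrays, a choice made after the data were seen, camera gave this list adjusted p = 6.67e-09, and adjusted p = 0.0443 with an estimated correlation. SVZ scores for it were 0.77, 0.36 and 0.45. Interferon and antigen presentation genes were higher in 2 of 16, Cxcl9 and H2-Aa (5 over the list alone and 0 without the 4 arrays; adjusted p = 2.19e-05, adjusted p = 0.799 with an estimated correlation). Against cortex tumors 0 of 12 T and NK cell genes passed (5 over the list alone, 2 without the 4 arrays; adjusted p = 0.000716, adjusted p = 0.567 with an estimated correlation).

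Against cortex tumors Lipg was the single gene that changed by limma, with 2101 genes at unadjusted p under 0.05. There were 53 changed after centring (47 higher, 6 lower), 29 after quantile normalization (15 and 14), and 2 with trend and robust settings. Centring moved the median of all genes from 0.09 to 0.19. The count was 539 (124 and 415) without GFAP cortex tumor 1, 4 without cortex tumor 2, 3 without SVZ tumor 2, 34 without SVZ tumor 3 and 2361 (945 and 1416) without the 4 arrays. Against hippocampus tumors 63 genes changed, 30 higher and 33 lower (85 and 60 after quantile normalization), and 134 (33 and 101) without the 4 arrays. With hippocampus tumors 1 to 4 only 2 were higher and 24 lower, and with the replicate number as a block 5 and 26. With tumors 5 to 7 only it was 4478 and 1170, so the balance of directions depended on which hippocampus tumors were used. The count against hippocampus tumors was 323 without hippocampus tumor 4, 37 without tumor 6, 28 without tumor 7, and 4, 3 and 106 without SVZ tumors 1, 2 and 3. Lipg kept its call each time, and every other named gene lost its own without SVZ tumor 1 or 2. The groups lay apart in 1695 genes (8.50%; chance 5.71%) against cortex and 849 (4.26%; chance 1.67%) against hippocampus tumors. Both counts were 0 with only the groups compared in the fit, and regrouping did not separate either from chance.

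The normal tissues differed in regional marker genes. Syna, an endogenous retroviral envelope gene, was 8.07-fold higher in hippocampus (log2 difference 3.01 ± 0.21, 4 arrays against 4, limma adjusted p = 8.69e-10). Also higher were the heparan sulfate enzyme gene Ndst4 9.88-fold, Shisa6 8.11-fold, the neuropeptide Y receptor Npy2r 7.41-fold, Cabp7 6.89-fold, Slc9a4 6.31-fold, Pcdh20 5.37-fold, Doc2b 4.74-fold and Spink8 4.73-fold. Dkkl1 was 7.10-fold lower (-2.83 ± 0.28, adjusted p = 4.01e-07). Myl4 (-2.40), the cholecystokinin receptor Cckbr (-2.16), Rasgef1b (-2.07), Hs3st2 (-2.03), Cobl (-2.02), Efna5 (-1.98), Exph5 (-1.97), the relaxin family receptor Rxfp2 (-1.82) and Foxp2 (-1.81) were lower. By limma 257 genes changed, 112 higher and 145 lower (169 without normal hippocampus 1), and 3656 (18.3%; chance 2.86%) kept the tissues apart. Hippocampus region genes were higher in 7 of 11 (7 over the list alone; camera adjusted p = 4.51e-32, adjusted p = 2.64e-06 with an estimated correlation), Prox1 by 2.09. Cortex region genes were lower in 4 of 11 (over the list alone 9 lower and 1 higher; adjusted p = 1.73e-15, adjusted p = 0.0052 with an estimated correlation). Ependymal and choroid plexus genes were higher in 2 of 12, Kl by 1.70 and Tmem212 by 0.81 (3; adjusted p = 1.47e-07, adjusted p = 0.0243 with an estimated correlation). Scores were 0.76 and 0.65 in normal hippocampus 1 and 2 and -0.05 and -0.11 in 3 and 4.

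**Figure D5:**
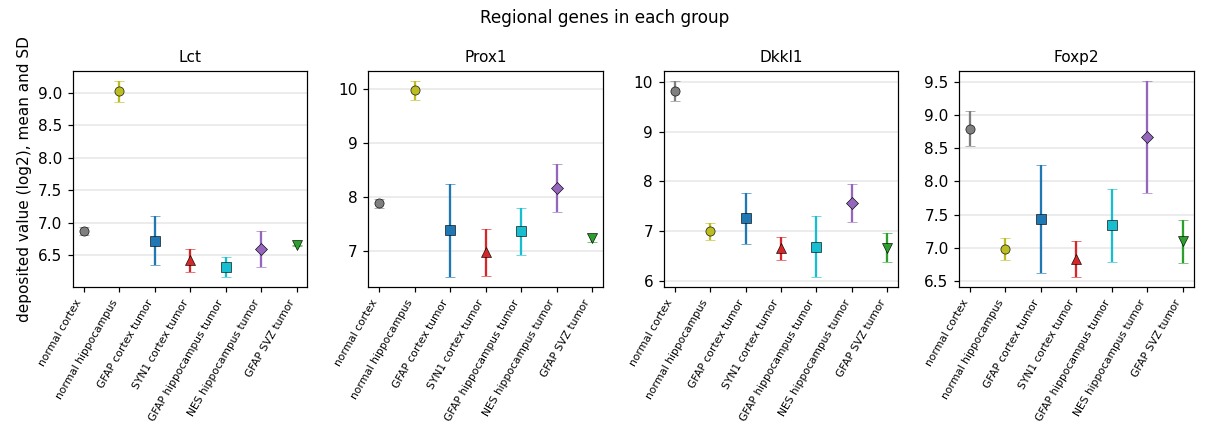
Regional marker genes in normal tissue and in tumors. Shown are the mean and SD of Lct, Prox1, Dkkl1 and Foxp2 in each group. Dkkl1 and Foxp2 differed by -2.83 and -1.81 log2 between normal hippocampus and normal cortex.

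The change from normal tissue to GFAP tumor differed by region for genes that set the normal tissues apart, among others. The interaction contains the normal hippocampus minus normal cortex difference with its sign reversed, from the same arrays. A gene that differs between the normal tissues and not between the tumors thus gets an interaction of the opposite sign. For Syna, Slc9a4 and Dkkl1 the normal differences were 3.01, 2.66 and -2.83, so their interactions are not a result apart from the normal contrast. Syna fell in hippocampus tumors (-3.22 log2, limma adjusted p = 8.67e-12) and differed by 0.23 in cortex tumors (adjusted p = 0.473), a negative interaction (-3.45 ± 0.28 log2, 4 groups of 4 to 7 arrays, limma adjusted p = 2.51e-08). The interaction was negative too for Slc9a4 (-3.01 ± 0.29, adjusted p = 4.73e-07), Ndst4 (-3.76), Npy2r (-3.39), Cabp7 (-3.21), Pcdh20 (-3.07) and Doc2b (-2.79). Dkkl1 (2.25 ± 0.38, adjusted p = 0.00164), Cckbr (2.15), Myl4 (1.99), the growth factor binding protein gene Igfbp6 (1.89), Rxfp2 (1.75 ± 0.21, adjusted p = 1.5e-05) and the neuropeptide gene Adcyap1 (1.74) had the opposite sign. By limma 167 genes had an interaction, 68 positive and 99 negative. With the replicate number as a block it was 542, 422 positive and 120 negative, and with GFAP hippocampus tumors 1 to 4 only 493 (384 and 109), so the balance of directions is not settled. After centring 112 were positive and 88 negative, which moved the median of all genes from 0.03 to 0.11. The count was 537 (347 and 190) without the 4 arrays, 270 without GFAP cortex tumor 1, 108 without GFAP cortex tumor 3 and 111 without normal cortex 1. Hippocampus region genes were negative in 7 of 11 (8 over the list alone, 6 without the 4 arrays; camera adjusted p = 3.81e-20, adjusted p = 0.000103 with an estimated correlation), Lct by -2.55 and Prox1 by -2.11. Cortex region genes were positive in 2 of 11 (5, with 2 negative, over the list alone; adjusted p = 0.00838, adjusted p = 0.896 with an estimated correlation). Hippocampus region scores were 0.67 in normal hippocampus and -0.67 in normal cortex, and -1.20 and -0.97 in the GFAP tumors of those regions. The hippocampus and cortex region lists name genes of these normal tissues, whose difference the interaction contains. Their shifts in the interaction are thus not a result apart from the normal contrast either.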

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

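The 7 tests of explanations in this part, and the mixtures with other genes or lists, were chosen only after the result they concern was seen, while the regroupings of arrays were planned before. Array measures were screened for single values far from their group with Dixon's test, 210 tests of 35 measures, where chance gives about 1 in 20 or 10.5; 16 passed, on 10 arrays.

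GFAP hippocampus tumors 5 to 7 lay apart from tumors 1 to 4 on the second component. Separate processing was tested with olfactory receptor genes, silent in brain: in 1.56% of 1027 such genes all 3 arrays lay outside the range of the other 27, against 8.70% of other genes and 0.049% by chance. That share is above chance and below other genes, so a processing difference and a biological one cannot be told apart; dates of hybridization, not used here, would keep or exclude the former. A smaller share of the tissue of tumors 1 to 4 was excluded as the whole explanation: with the share set by cell cycle genes the neuron score lay below the mixture with normal hippocampus, at -1.40 log2 (SD 0.685, 3 arrays), and at -1.22 (SD 0.525) with the share from 1257 higher genes outside the lists. No biological explanation was tested, and a smaller share together with a processing difference stays open.

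GFAP cortex tumor 1 lay apart from GFAP cortex tumors 2 to 4. Its olfactory receptor genes had a median of 6.08, against 5.19 to 5.26 in tumors 2 to 4 and at most 5.91 in any other array, a sign of raised background. Background or compressed signal was excluded as the whole explanation, as neuron genes lay at -1.99 log2 (SD 1.46, 22 genes) and bright matrix genes at 1.69 log2 (SD 0.98, 19 genes) from the curve through genes outside the lists. Less surrounding brain around the same kind of tumor stays open: the microglia and macrophage score was lower than in the others, at -0.82 log2 (SD 0.357, 3 arrays), but raised background would lower it too, and from the same curve these genes lay at -0.175 (SD 0.728, 20 genes), so the 2 cannot be told apart. No biological explanation was tested, and how much of the departure is technical stays open.

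NES tumors differed from normal hippocampus in 1706 genes and GFAP hippocampus tumors in 8245. Dilution of the profile of GFAP tumors 1 to 4 by normal hippocampus, with the share fitted on 3079 called genes outside the lists, fits the neuron genes, whose score differed from the mixture by 0.10 log2 (SD 0.197, 4 arrays; 0.08, SD 0.267, with the 1257 higher genes alone), at tumor shares of 95.2%, 52.7%, 24.8% and 31.9%. Dilution alone was excluded by interferon and antigen presentation genes, which lay 1.12 log2 (SD 0.116) above the mixture. In 10 of 27 lists all 4 arrays lay on the same side of the mixture, with a mean difference larger than the SD. Among these were oligodendrocyte precursor genes (0.70) and hippocampus region genes (-0.78). How many lists would do so by chance was not tested. A larger normal part in NES tumors 2 to 4 may therefore account for the neuron genes, while these lists stay unexplained. A promoter effect on the interferon genes was not tested apart and stays open: between NES and GFAP hippocampus tumors 1 of 16 was called (0 without the 4 arrays), and their median was higher in NES tumors by 0.85 log2 (camera adjusted p = 0.0135, adjusted p = 0.599 with an estimated correlation), or by 0.46 without the 4 arrays.

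Regrouping the arrays tested whether chance can be excluded as the source of each count. Chance is excluded for GFAP cortex tumors (5536 genes, 1 of 35 groupings with as many, highest other 0), SYN1 cortex tumors (7723, 1 of 35, highest other 0), NES hippocampus tumors (1706, 1 of 35, highest other 0) and normal tissues (257, 1 of 35, highest other 0). It is excluded for GFAP hippocampus tumors (8245, 1 of 100). The highest other count there, 6411, came from putting tumors 5 to 7 with the normal arrays. These shares, 0.029 for 1 of 35 and 0.01 for 1 of 100, were not adjusted over the contrasts. For the interaction (167, 2 of 100) the share of 0.02 was under the limit of 0.05 set beforehand. The interaction is still left undecided here, as another grouping called 589. Regrouping also did not test the interaction apart from the difference between normal tissues that the interaction contains. Chance is not excluded for SYN1 against GFAP (35, 6 of 35), where 1468 genes were called with GFAP cortex tumor 1 among the SYN1 tumors. For NES against GFAP (1637, 5 of 100) the highest other was 5886, with NES tumor 4 beside GFAP hippocampus tumors 5 to 7. For hippocampus against cortex tumors (534, 10 of 100) it was 8070, with hippocampus tumors 5 to 7 beside cortex tumor 1. For SVZ against cortex tumors (1, 10 of 35) it was 2789, with cortex tumors 2 to 4 against the rest, and for SVZ against hippocampus tumors (63, 12 of 100) 6975, with tumors 5 to 7 against the rest. In these 5 contrasts between tumors the highest other grouping called several times the real count, which points to a structure of the samples. Each of these groupings set GFAP cortex tumor 1 or GFAP hippocampus tumors 5 to 7 apart from the rest of their own group, with SYN1 tumors 1 to 3 in the first case and NES tumor 4 in the second. Among the 16 groupings of hippocampus and cortex tumors that part all numbered pairs 4 called as many, highest other 3992; with the number as a block 1 of 8 did (1954, highest other 0).

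In the Dixon screen GFAP cortex tumor 1 had an interquartile range of 1.88 (2.74 to 2.81 in the others), an Rb1 level of 7.72 (9.68 to 9.97) and a promoter and vector gene score of -0.97 (0.71 to 0.98). GFAP hippocampus tumor 5 had a Cdkn2a level of 8.17 (9.77 to 10.19), a hypoxia score of 0.07 (0.98 to 1.29) and a striatum and SVZ score of 0.50 (-1.05 to -0.61). GFAP hippocampus tumor 3 had an oligodendrocyte precursor score of 0.88 (-0.58 to -0.02). NES tumor 3 had an Nf1 level of 11.13 (10.62 to 10.67), and NES tumor 1 an oligodendrocyte score of -1.03 (-0.03 to 0.11) and a T and NK cell score of 0.48 (0.16 to 0.20). SYN1 tumor 2 had a mesenchymal score of 1.95 (2.12 to 2.15) and SYN1 tumor 3 a neural subtype score of -3.06 (-1.99 to -1.93). Normal cortex 3 had a microglia score of -0.11 (0.06 to 0.08) and a classical subtype score of -0.028 (0.013 to 0.017). Normal hippocampus 1 had a proneural score of 0.15 (-0.05 to -0.02) and normal hippocampus 3 a median of 7.19 (7.20 in the others).

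By limma the change from normal to GFAP tumor differed between regions in 167 genes. That count was left undecided by regrouping and contains the difference between the normal tissues. Of the 13767 probe sets without a single gene symbol, 784 changed in GFAP cortex tumors, 2597 in GFAP hippocampus tumors, 1928 in SYN1 cortex tumors and 165 in NES tumors.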

How the results depend on the processing

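The alternatives chosen only after the data were seen are leaving out the 4 arrays that stand apart, GFAP hippocampus tumors 5 to 7 only, the promoter genes without GFAP cortex tumor 1, and the mixture of tumor and normal tissue with its share from higher genes alone and over all lists. No named gene changed sign under any alternative, and no list passed in opposite directions. Without the 4 arrays, lists that passed with all arrays lost that and their medians turned for mural cell and fibroblast genes in hippocampus against cortex tumors (-0.29 to 0.10) and the interaction (-0.42 to 0.04), and for matrix genes in SVZ against cortex tumors (-0.20 to 0.12). Other lists turned and passed by camera only without the 4: neuron (0.07 to -0.70), astrocyte, oligodendrocyte precursor and neural subtype genes in hippocampus against cortex tumors, neuron (0.20 to -0.54) and astrocyte genes in the interaction, and cell cycle genes in SVZ against hippocampus tumors (0.14 to -0.46). None of these passed with an estimated correlation. Of the 194 named genes 180 were still tested without dim genes and all of these kept their calls. The others were among the dim genes left out. Calls were lost by 7 after centring, 30 after quantile normalization, 79 with only the groups compared and 22 with the replicate block. Trend and robust settings took the call from 9, array weights from 4 and the mean of probe sets from 1. Of 297 list results, 128 lost their calls with an estimated correlation and 71 with fry, 8 after centring and 17 after quantile normalization. The 297 include results with no call to lose, so these counts are not shares of the calls. Few of the list results given above passed with both correlations. The cause was not tested for any of the values that moved, except that stricter thresholds lower counts by construction.

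A change of at least 2-fold took the counts to 2830 for GFAP cortex tumors, 3248 for GFAP hippocampus tumors, 4283 for SYN1 and 1001 for NES tumors against normal tissue, 21 for SYN1 against GFAP, 506 for NES against GFAP, 68 for hippocampus against cortex tumors, 21 for SVZ against hippocampus tumors and 150 for the normal tissues; the interaction had 121. Genes shared in direction were 2180 for the GFAP pair and 836 for the SYN1 and NES pair. Adjusted p under 0.01 left 3368, 5586, 5907 and 741 in the tumor groups against normal tissue, 1 for SYN1 against GFAP, 5 for NES against GFAP, 50 for hippocampus against cortex tumors, 1 for SVZ against hippocampus tumors, 149 for normal tissues and 85 for the interaction. The GFAP and SYN1 contrasts with normal tissue kept most calls at that level, and those between tumors few.

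Centring moved SYN1 against GFAP from 35 to 128, hippocampus against cortex tumors from 534 to 928 and SVZ against cortex tumors from 1 to 53. Quantile normalization gave 13, 141 and 29 for these and 145 for SVZ against hippocampus tumors. Leaving out dim genes gave 357 for hippocampus against cortex tumors. Trend and robust settings gave 13 for SYN1 against GFAP and 2 for SVZ against cortex tumors.

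With only the groups compared, SYN1 against GFAP had 4 genes, NES against GFAP 0, hippocampus against cortex tumors 0, and SVZ tumors 0 against either, while NES tumors against normal had 3088 and the normal tissues 2768. SYN1 tumors against normal had 9783. Fewer arrays in a fit leave fewer degrees of freedom, which tends to lower counts, so the rises argue against that cause for the contrasts that rose. The normal arrays varied less than the tumors. Their lowest correlations within a group were 0.991 and 0.994, against 0.832 to 0.956 in the tumor groups. Whether the pooled spread or the fewer arrays lowered the counts between tumors was not tested. Each contrast between tumors rests on that pooled spread, which includes the normal arrays. It may thus be too small for the tumors, and the p-values between tumors too low. Array weights raised GFAP cortex tumors to 10610, NES tumors to 7723, SYN1 against GFAP to 2489, NES against GFAP to 4715, hippocampus against cortex tumors to 1075, SVZ tumors to 5173 and 528, normal tissues to 2645 and the interaction to 1696; GFAP cortex tumor 1 had a weight of 0.105 and GFAP hippocampus tumors 5 to 7 0.135, 0.249 and 0.228.

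The replicate number as a block gave 2885 for NES tumors against normal, 950 for SYN1 against GFAP, 2744 for NES against GFAP, 1954 for hippocampus against cortex tumors, 123 for SVZ against cortex tumors, 31 for SVZ against hippocampus tumors, 389 for normal tissues and 542 for the interaction. The block leaves GFAP hippocampus tumors 5 to 7 without partners in other groups, and with tumors 1 to 4 only and no block the counts were 2174 for NES against GFAP, 1924 for hippocampus against cortex tumors, 26 for SVZ against hippocampus tumors and 493 for the interaction. With tumors 5 to 7 only, NES against GFAP had 6742 (5445 higher and 1297 lower) and hippocampus against cortex 4965 (1561 and 3404). In that setting SVZ against hippocampus had 5648 (4478 and 1170) and the interaction 2362. Without the 4 arrays that stand apart SYN1 against GFAP had 2655, NES against GFAP 4218, hippocampus against cortex tumors 2090, SVZ tumors 2361 and 134, and the interaction 537.

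Leaving out each array in turn gave 4269 to 6120 for GFAP cortex tumors, 6880 to 8836 for GFAP hippocampus tumors, 6878 to 7434 for SYN1 tumors and 702 to 1863 for NES tumors against normal tissue. It gave 1 to 1132 for SYN1 against GFAP, 6 to 3398 for NES against GFAP, 205 to 1421 for hippocampus against cortex tumors, 1 to 539 and 3 to 323 for SVZ against cortex and hippocampus tumors, 169 to 200 for the normal tissues and 108 to 270 for the interaction. The tumor against normal counts of GFAP and SYN1 tumors never moved by more than 1.5-fold, and the contrasts between tumors depended on single arrays. Signal over background compresses differences of dim genes, which limits what can be called among them.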

Other observations

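Lists not yet described were mixed. Targets of p53, a tumor suppressor, were higher in 4 of 14 genes and lower in 1 in GFAP cortex tumors (4 and 1 adjusted over the list alone, 6 and 1 without the 4 arrays; camera adjusted p = 0.0268, adjusted p = 0.392 with an estimated correlation). In GFAP hippocampus tumors 6 were higher and 1 lower (6 and 1; adjusted p = 0.0351, adjusted p = 0.484 with an estimated correlation), and 10 were higher without the 4 arrays that stand apart. Eda2r, a death receptor gene, was higher by 1.39 in GFAP cortex tumors, 1.503 in GFAP hippocampus tumors, 1.82 in SYN1 tumors and 1.34 in NES tumors. Classical subtype genes were higher in 4 of 14 and lower in 1 in GFAP cortex tumors (5 and 2, and 4 and 1 without the 4 arrays; adjusted p = 0.0292, adjusted p = 0.297 with an estimated correlation), with Egfr up by 1.27. Proneural genes were lower in 1 of 15 (0 over the list alone; adjusted p = 0.755), but without the 4 arrays 3 were higher and 0 lower. With all arrays the median log2 difference was -0.01 and the mean -0.13 while camera ranked the list up.

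B cell and neutrophil genes were higher in 2 of 11 in GFAP cortex tumors (2 over the list alone, 2 without the 4 arrays; camera adjusted p = 0.0135, adjusted p = 0.297 with an estimated correlation), with Cxcr2, a neutrophil chemokine receptor gene, up by 1.69. Neither of the 2 measured red blood cell genes passed (adjusted p = 0.844). Oligodendrocyte precursor genes were lower in 1 of 10 (0 over the list alone; adjusted p = 0.913) with a median of -0.30 and a mean of -0.22 while camera ranked them up. Astrocyte genes were lower in 3 of 14 (2; adjusted p = 0.188). Without the 4 arrays each list had 1 higher and 0 lower, with medians of 0.18 for oligodendrocyte precursor genes and -0.34 for astrocyte genes. The AP-1 gene Fosl1 rose by 2.42 in GFAP cortex tumors and by 3.10 in SYN1 tumors, and Egr1 of the same RAS and MAPK response list fell by 1.61 and 1.74; in GFAP cortex tumors 7 of its 18 genes were higher and 2 lower (8 and 2 over the list alone and without the 4 arrays; adjusted p = 0.0103, adjusted p = 0.51 with an estimated correlation).

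Striatum and SVZ region scores varied within groups whose label names another region. They were -0.08, -0.05, 0.77 and 0.52 in normal cortex 1 to 4 and -0.82, 0.56, 1.42 and 0.30 in NES tumors 1 to 4. The sites of dissection are not given in the sources used here. NES against GFAP hippocampus tumors had 3 of 13 such genes higher (8 over the list alone and 8 without the 4 arrays; camera adjusted p = 0.000196, adjusted p = 0.513 with an estimated correlation).

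NES tumor 1 differed from the other NES tumors in several scores. Its fitted tumor share was 95.2% against 24.8% to 52.7%, and its neuron and oligodendrocyte scores were the lowest of the 4, at -1.57 and -1.03. A smaller part of normal tissue in that sample is possible. Tissue shares were not measured, and the mixture behind the fitted share was excluded as the sole account of NES tumors. The count against normal hippocampus, 1706 genes with all 4, was 702 without NES tumor 1 and 1154, 1863 and 1840 without NES tumors 2, 3 and 4, so it rested most on NES tumor 1.

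What the data leave open is whether promoters or samples set the tumors apart. More arrays of each promoter in 1 region, processed together, would separate them, and a count of tumor cells in each sample would show how far the dilution fitted here holds.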
